A study of Rattus norvegicus with 10 samples.

How the data were processed

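Total RNA of 10 rat fetal kidney samples, taken on day 22 of gestation, was measured on 1-colour Affymetrix rat expression arrays, 1 array per sample. Per the labels, 5 samples came from normal mothers kept on a regular diet (replicates 1 to 5, the normal group). The other 5 came from Wistar mothers of 200 to 280 g that carried a sustained-release insulin implant of 2 mm under the skin (replicates 6 to 10, the hyperinsulinemic group). Kidneys were frozen and RNA was extracted with a phenol-based reagent, per the labels' protocols. The labels used here name no litter, mother, sex, batch or date for a sample. The p-values therefore measure only the spread between these samples, which may be technical in part, and littermates would make them too small.

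The deposited values were linear intensity values, 1 signal per probe set and array, and the submitters' processing notes name MAS5, the Affymetrix algorithm that summarises the probes of a set and scales each array. Its version and settings were not given in the sources used here. The trimmed mean of every array, leaving out 2% at each end, was 250, so the arrays had been scaled to 1 target, and the values were used as deposited. No detection calls were used. The table held 15923 probe sets. GEO's platform annotation gave 1 gene symbol for 12789 of them and several for 312, and 2822 were unnamed here; no gene was named from a probe set with several symbols. By Entrez identifier, 12754 probe sets matched the gene table of the GRCr8 assembly, which was used for names and for X or Y linkage only. No coordinates are given, since no build was named for the array.

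Values were transformed as log2(signal + 16), so fold changes are on that scale and understate the change of dim genes. The 57 Affymetrix control probe sets were left out. A probe set was tested when its signal reached the array's 40th percentile on at least 5 of the 10 arrays, which left 9601 probe sets and 7267 genes. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Single values were compared with exact two-sided permutation tests, for which 5 against 5 arrays cannot give a p below 0.00794. The number of arrays limits the precision.

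Before the data were examined, 33 gene lists of cell types, pathways and neighbouring tissues had been fixed, together with the tests and most alternatives. Lists with at least 5 tested genes, 31 in all, were tested against all other genes with limma's camera at its preset correlation of 0.01, with the brightest probe set per gene. The list of adipose tissue had 3 tested genes and that of sex-linked genes had 0, and neither was tested. Camera was run in its plain form, without an intensity trend in the variance, and with that trend. The plan did not settle which form to use. The plain form was run first and is the one reported; the form with the trend had been set as the main one for a time after the plain results were seen, and was then moved to the alternatives. The forms gave 10 and 13 lists, and they differ in how often other splits of the arrays gave as many lists, so both are given in the closing section.

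Genes were named by a rule fixed in advance: per direction up to 12 genes that passed or, failing that, had the smallest unadjusted p and a fold of at least 1.5; the 4 members with the smallest p in the direction of each list that passed; at most 2 members of any other list; and 12 genes of the insulin, renin-angiotensin and kidney development systems, not all of which are reported here. For lists that did not pass, only members with an unadjusted p under 0.05 were taken, a reading made after a first fit had been seen.

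The alternatives were other normalizations, pseudocounts of 1 and 32, other filters, other variance models, array weights, the ratio of 3' to 5' Gapdh control signals as a covariate, camera with an estimated correlation, fry, the mean of a gene's probe sets, a rank test and leaving out each array. Added after the data were seen were the omission of the 2 arrays with the most Alb, the mean of the liver list as a covariate, and camera with an intensity trend. The tests were tried on data simulated for this comparison from the fitted means and residual spread of the 9601 probe sets, with 200 of them changed. Of those changed by a log2 value of 0.5, 82.1% were recovered, of those changed by 1, 98.5%, and of those changed by 2, 100%, while 8 unchanged probe sets were called. With 200 probe sets changed, the adjusted threshold is easier to reach than with few. These rates therefore do not carry over to the real comparison, where 1 probe set passed. Camera called 0 lists on unchanged data. The simulation drew probe sets independently and so does not test how camera behaves when genes are correlated. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.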

Results

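The study asked how the fetal kidney transcriptome differs when growth is restricted by excess insulin in the mother. In each group 5 kidney samples were taken, from fetuses of normal mothers and from growth-restricted fetuses of rats with insulin implants, on day 22 of gestation, close to birth. Each array gave a MAS5 signal for 15923 probe sets, with a median signal of 135 ± 1.75 in the normal group and 135 ± 3.02 in the hyperinsulinemic group (SD, n = 5 each). Pairwise correlations of log2 signals ran from 0.970 to 0.989, with a median of 0.982 within groups and 0.982 between groups. Hyperinsulinemic replicate 6 stood apart: its median correlation with the others was 0.974, against 0.980 to 0.984 for the other arrays, and its score on the first principal component (21.8% of the variance) was 19.5, against -7.44 to 0.484. On the second component (16.4%) hyperinsulinemic replicate 10 was lowest, at -13.5, against -7.04 to 9.35. The 3' to 5' ratio of the Gapdh controls, a sign of RNA integrity, was 1.07 ± 0.0505 and 1.09 ± 0.0649 (SD, n = 5 each, exact permutation p = 0.746). Values after ± are SDs for signals and standard errors for log2 differences, and each group has 5 arrays unless stated.

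Rabepk, which encodes a Rab9 effector of endosome-to-Golgi transport, rose in kidneys of the hyperinsulinemic group. Its signal was 281 ± 24.0 in the normal group and 432 ± 47.7 in the hyperinsulinemic group, a log2 difference of 0.59 ± 0.08 (limma, adjusted p = 0.0315), and every hyperinsulinemic array lay above every normal one. It was the 1 probe set of 9601 that passed; 1 was higher and 0 were lower. The urinary protein gene Rup2 went from 50.3 ± 39.7 to 798 ± 799, a log2 difference of 3.35 ± 0.51, and did not pass (limma, adjusted p = 0.0546). It passed with arrays shifted to a common median (limma, adjusted p = 0.0412), with array weights (0.0158) and without hyperinsulinemic replicate 6 (log2 difference 2.87, adjusted p = 0.0321) or 10 (3.72, adjusted p = 0.0297). Without replicate 6 the count was 4 probe sets: Rabepk, 2 of Rup2 and, lower, LOC100911253 (-0.51, adjusted p = 0.0365); without normal replicate 5 it was 2, Rabepk and Lum. Another 3 Rup2 probe sets gave smaller log2 differences, of 2.10, 2.10 and, below the filter, 1.31. The X-linked gene Pbdc1 differed by 0.34 ± 0.06 (limma, adjusted p = 0.0907). An unadjusted p under 0.05 was reached by 515 probe sets, 234 higher and 281 lower, where chance alone would give 480. The groups did not overlap for 100 probe sets, or 1.04%, against 0.794% by chance. The log2 difference of Rabepk stayed between 0.53 and 0.63 when each array was left out, but its call was lost without normal replicate 1, 2, 3 or 4 (adjusted p = 0.0602, 0.0716, 0.0903 and 0.0899) or hyperinsulinemic replicate 7, 9 or 10 (0.113, 0.0628 and 0.0659). The call was also lost without the intensity trend (0.59, limma adjusted p = 0.0676). It was lost too without the 2 arrays with the most Alb (log2 difference 0.62, limma adjusted p = 0.0767) and with the liver score as a covariate (0.64, 0.0780). The exact rank test passed 0 probe sets, with 362 at an unadjusted p under 0.05. Its smallest p is 0.00794, reached only by the 100 that did not overlap, which are too few to survive adjustment over 9601. The rank test therefore says nothing about Rabepk, and the 480 expected above does not apply to its coarse p-values.

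Among the genes with the largest differences that did not pass, Eif2s3, an X-linked translation initiation factor, stood at 356 ± 76.8 and 581 ± 61.4 (log2 difference 0.70 ± 0.13, limma adjusted p = 0.133). Slc37a1, a sugar phosphate transporter gene, stood at 67.8 ± 46.7 and 125 ± 20. On the lower side, the tissue factor gene F3 differed by -0.70 ± 0.15, the alarmin Il33 by -0.60 ± 0.13, the calcium-binding protein gene S100a4 by -0.64 ± 0.15 and Spp2 by -0.64 ± 0.18. Their adjusted p-values in limma were 0.264, 0.264, 0.393 and 0.676. Gc, which encodes the vitamin D binding protein, stood at 79.3 ± 16.2 and 219 ± 206, and the complement gene C3 at 67.3 ± 46.1 and 227 ± 240. Both encode plasma proteins and were highest in hyperinsulinemic replicate 6, at 582 and 646, the array with the most Alb; without it the hyperinsulinemic means were 128 and 122, and the log2 differences 0.57 ± 0.17 and 0.78 ± 0.32. The remaining genes named by size are described with their lists.

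**Figure D1:**
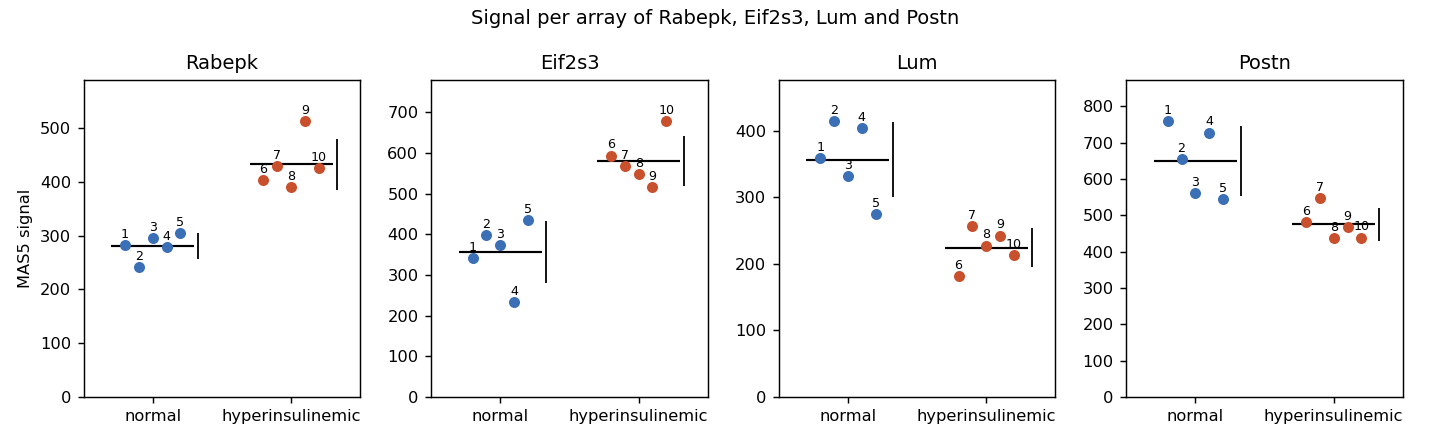
Signal per array of Rabepk, Eif2s3, Lum and Postn in the normal and hyperinsulinemic groups, on linear axes that start at 0. Points are arrays with their replicate numbers, horizontal lines are means and vertical lines are SDs; Rabepk, with means of 281 and 432, is the gene of these that passed the test.

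Genes of the interstitial stroma, the connective tissue between the tubules, fell as a group in the hyperinsulinemic kidneys. Of 18 measured members, 14 were lower and 4 higher, with a median log2 difference of -0.14 (camera, adjusted p = 5.32e-05). This was the 1 list whose call held with an estimated correlation (adjusted p = 0.0316). The collagen-binding proteoglycan gene Lum stood at 357 ± 57.0 and 224 ± 29.1 (log2 difference -0.63 ± 0.11), the matricellular gene Postn at 649 ± 96.0 and 475 ± 45.5, Col14a1 at 578 ± 54.0 and 476 ± 44.0, and Dcn at 1803 ± 44.5 and 1632 ± 119. With all arrays none of these passed alone over all probe sets, and 3 did when adjusted over the list alone; without normal replicate 5, Lum passed over all probe sets, at -0.71 (limma, adjusted p = 0.0310). Among the 4 members that were higher were Cxcl12, at a log2 difference of 0.08, and the retinoic acid enzyme gene Aldh1a2, at 0.08. The extracellular matrix list also fell, with 26 of 36 members lower and a median of -0.05 (camera, adjusted p = 0.00398), but its adjusted p was 0.25 with an estimated correlation. Its leading members were the collagen cross-linking enzyme gene Lox (-0.30 ± 0.09), Timp2 (-0.22 ± 0.10), Col1a1 (-0.17 ± 0.08) and Col1a2 (-0.14 ± 0.06), and 0 passed when adjusted over the list alone. Liver transcripts, described further on, moved with both lists: with the liver score as a covariate the median of the stroma list was -0.06 (camera, adjusted p = 0.00275) and that of the matrix list -0.03 (0.0134), and without hyperinsulinemic replicate 6 that of the matrix list was -0.03.

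Tubule genes were lower as well. The proximal tubule list fell, with 26 of 31 members lower and a median of -0.06 (camera, adjusted p = 0.000213; adjusted p = 0.27 with an estimated correlation). Its leading members were the glucose transporter genes Slc5a2 (-0.29 ± 0.10) and Slc2a2 (-0.16 ± 0.06), the fatty acid transporter gene Slc27a2 (-0.18 ± 0.08) and the amino acid transporter gene Slc7a9 (-0.19 ± 0.08). The loop of Henle and distal tubule list fell, with 9 of 11 members lower and a median of -0.13 (camera, adjusted p = 0.00811; adjusted p = 0.117 with an estimated correlation). The tight junction gene Cldn10 stood at 601 ± 36.4 and 492 ± 55.0, and was the 1 member to pass when adjusted over the list alone; Ptger3 (-0.39 ± 0.19), Slc8a1 (-0.13 ± 0.07) and Umod (-0.17 ± 0.14) followed, the last at -0.04 without hyperinsulinemic replicate 8, -0.11 without replicate 7 and -0.27 without replicate 10. In the ureteric bud and collecting duct list, which did not pass (camera, adjusted p = 0.709), the water channel genes Aqp2 and Aqp3 differed by 0.45 ± 0.11 and 0.18 ± 0.06. The loop of Henle list lost its call without the 2 arrays with the most Alb (adjusted p = 0.0777), and with the liver score as a covariate (adjusted p = 0.0607). Its median was -0.10 with that covariate, -0.05 without those 2 arrays, -0.08 without normal replicate 4 and -0.07 and -0.08 without hyperinsulinemic replicates 6 and 8, while that of the proximal tubule list was -0.10 without replicate 8.

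Genes of lipid synthesis and of the cell cycle rose as groups. In the sterol and fatty acid synthesis list, 17 of 23 members were higher, with a median of 0.06 (camera, adjusted p = 0.000548; adjusted p = 0.25 with an estimated correlation). The 4 members that passed when adjusted over the list alone belong to fatty acid synthesis: Fasn (704 ± 67.7 and 853 ± 70.1), Acaca (335 ± 14.7 and 388 ± 19.3), their regulator Srebf1 (318 ± 52.6 and 404 ± 42.4) and the desaturase gene Scd2 (2184 ± 182 and 2648 ± 372). The median of the list was 0.04 with the liver score as a covariate (camera, adjusted p = 0.0165), 0.03 without normal replicate 5, 0.10 without normal replicate 1 and 0.11 without hyperinsulinemic replicate 10. In the list of fatty acid oxidation, which did not pass (camera, adjusted p = 0.0968), Cpt1a differed by -0.20 ± 0.06 and Cyp4a3 by -0.31 ± 0.09. The cell cycle and DNA replication list had 29 of 37 members higher and a median of 0.07 (camera, adjusted p = 0.00298; adjusted p = 0.071 with an estimated correlation). Its leading members were Ccne1 (0.25 ± 0.11), the replication licensing genes Mcm3 (0.13 ± 0.06) and Mcm7 (0.12 ± 0.05), and Top2a (0.11 ± 0.06), and 0 passed when adjusted over the list alone.

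The hypoxia-responsive list fell, with 15 of 21 members lower and a median of -0.06 (camera, adjusted p = 0.00826; adjusted p = 0.42 with an estimated correlation). Its leading members were the growth factor binding protein gene Igfbp3 (-0.30 ± 0.09) and Lox, which is a matrix enzyme, then Ankrd37 (-0.34 ± 0.16) and Bnip3 (-0.18 ± 0.09); 2 members passed when adjusted over the list alone. Immediate early genes fell, 10 of 16 being lower, with a median of -0.06 (camera, adjusted p = 0.0387; adjusted p = 0.27 with an estimated correlation). Ccn1 (-0.57 ± 0.21), Gadd45b (-0.23 ± 0.13), Egr1 (-0.21 ± 0.09) and Dusp6 (-0.17 ± 0.07) led it. The list of peripheral nerve and neurons fell, with 5 of 6 members lower and a median of -0.11 (camera, adjusted p = 0.0417; adjusted p = 0.25 with an estimated correlation), led by Rtn1 (-0.17 ± 0.10), Pmp22 (-0.14 ± 0.06), Nefl (-0.12 ± 0.09) and Nefm (-0.09 ± 0.08). In these last 2 lists 0 members passed when adjusted over the list alone. Each call was lost without some single arrays: the hypoxia list had an adjusted p of 0.345 without normal replicate 3 and 0.0536 without hyperinsulinemic replicate 9, the immediate early list 0.119 and 0.149 without normal replicates 2 and 3 and 0.0599, 0.139 and 0.127 without hyperinsulinemic replicates 6, 9 and 10, and the nerve list 0.0551 and 0.109 without normal replicates 3 and 4 and 0.124, 0.0545, 0.0934 and 0.0673 without hyperinsulinemic replicates 6, 7, 8 and 10. The immediate early and nerve calls lay near the threshold with all arrays, and other settings also ended them. Camera's adjusted p was 0.0545 for both with the Gapdh covariate and 0.129 for both without a filter. With the stricter filter it was 0.493 for immediate early genes. With the liver score as a covariate all 3 calls were lost (adjusted p = 0.252, 0.167 and 0.167), at medians of -0.02 for hypoxia, -0.02 for immediate early and -0.12 for nerve genes.

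**Figure D2:**
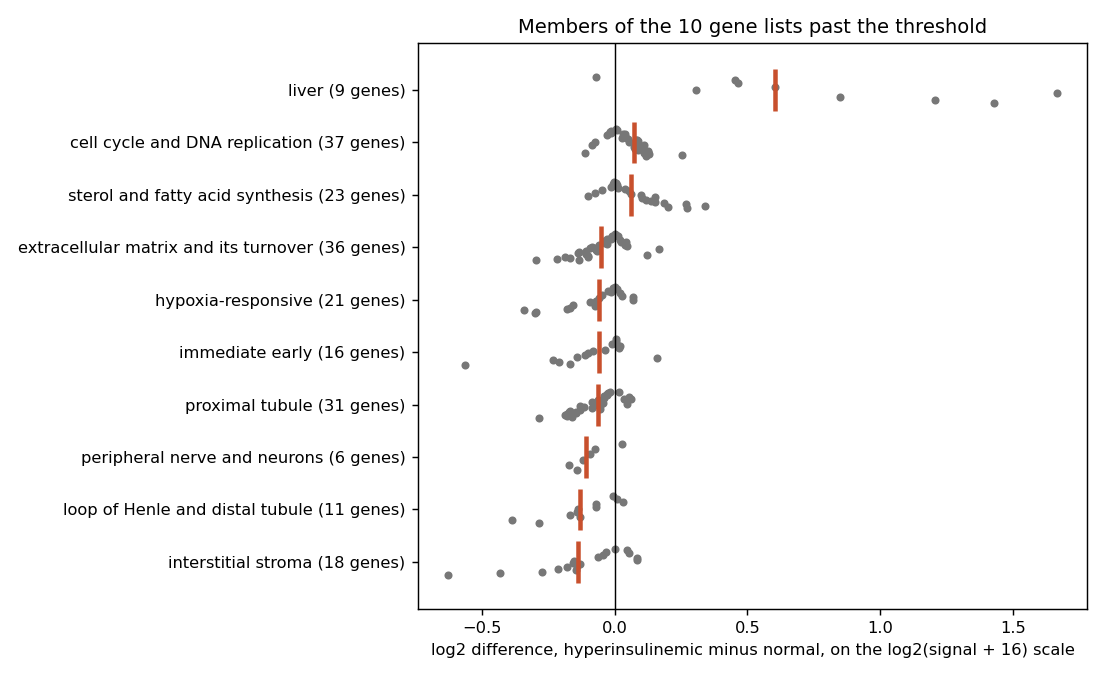
Log2 differences, hyperinsulinemic minus normal, of the tested members of the 10 lists that passed camera at its preset correlation. Grey points are genes, the red bars are list medians, from 0.60 for liver genes to -0.14 for interstitial stroma.

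Transcripts of the liver, a neighbouring organ, were higher in kidneys of the hyperinsulinemic group. In the fixed liver list 8 of 9 tested members were higher, with a median of 0.60 (camera, adjusted p = 2.6e-05; adjusted p = 0.266 with an estimated correlation), and 2 passed when adjusted over the list alone. The haemoglobin scavenger gene Hp stood at 120 ± 44.1 and 444 ± 420, the fibrinogen gene Fgg at 69.1 ± 37.4 and 225 ± 222, the albumin gene Alb at 209 ± 354 and 548 ± 679, and Serpina1 at 94.7 ± 60.5 and 150 ± 73.6. The transthyretin gene Ttr differed by 0.85 ± 0.33. Afp, an abundant transcript of fetal liver, stood at 886 ± 69.5 and 848 ± 132. Single arrays carried much of the signal: Alb was 1742 in hyperinsulinemic replicate 6 and 842 in normal replicate 4, and between 42.9 and 436 on all others. Without hyperinsulinemic replicate 6 the median of the list was 0.39, and the log2 differences were 0.99 for Hp, 0.77 for Fgg, 1.08 for Alb, 0.39 for Serpina1 and 0.52 for Ttr, against 1.21 for Fgg and 1.67 for Alb with all arrays. A score of liver genes was 6.14 ± 0.47 in the normal group and 6.81 ± 0.74 in the hyperinsulinemic group as a mean log2 signal (SD, n = 5 each, exact permutation p = 0.119; adjusted p = 0.691 by Benjamini-Hochberg over 6 array measures).

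The X-inactivation transcript Xist, which is made in cells with more than one X chromosome, separated the groups. It lay below the filter for the test, at 1.2 ± 0.485 in the normal group and 56.9 ± 10.3 in the hyperinsulinemic group (SD, n = 5 each, exact permutation p = 0.00794, the smallest that 5 against 5 arrays can give). Normal arrays ran from 0.8 to 2 and hyperinsulinemic arrays from 42.4 to 70.5. The labels give no fetal sex, so every comparison above is also a comparison between samples with low and with high Xist. A sex covariate could not be fitted, because the arrays with high Xist were exactly the hyperinsulinemic group. The Y-linked gene Sry, near the floor of the array, stood at 17.9 ± 5.74 and 12.4 ± 9.67 (SD, n = 5 each, exact permutation p = 0.254).

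**Figure D3:**
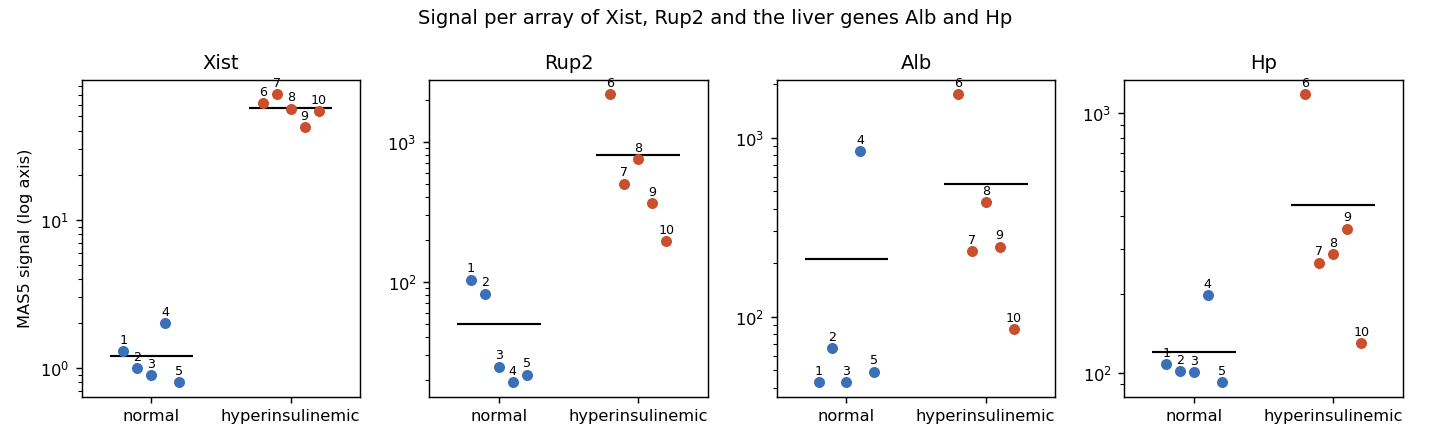
Signal per array of Xist, Rup2, Alb and Hp in the normal and hyperinsulinemic groups, on log axes. Points are arrays with their replicate numbers and horizontal lines are means; Xist runs from 0.8 to 2 in the normal group and from 42.4 to 70.5 in the hyperinsulinemic group, while Alb is at 842 in normal replicate 4.

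Other groups of genes did not pass. Genes of the insulin and insulin-like growth factor axis (camera, adjusted p = 0.264) included Igfbp3 and the growth hormone receptor gene Ghr (-0.31 ± 0.13). The insulin receptor gene Insr differed by -0.02 ± 0.09 and Igf2 by -0.03 ± 0.08. The renin-angiotensin-aldosterone list had an adjusted p of 0.295 with camera; Agtr1a differed by -0.05 ± 0.06 and the X-linked gene Agtr2 by -0.19 ± 0.10. Nephron progenitor genes (camera, adjusted p = 0.909) and podocyte genes (0.73) had medians of 0.01 and 0.02, and Wt1 differed by 0.11 ± 0.06. Igf1r, Agt, Ace and Gdnf were below the filter, and Pax2 and Six2 were not analysed here.

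Erythroid genes (camera, adjusted p = 0.0517), ribosomal protein genes (0.0543) and genes of smooth muscle and mesangium (0.0617) lay just above the threshold, and passed under some of the alternatives. In the last list the contractile genes Tagln and Des went opposite ways, at -0.42 ± 0.12 and 0.32 ± 0.09. Des also led the skeletal muscle list (0.511). In the glucocorticoid-responsive list (0.206) Txnip, a gene of glucose sensing, stood at 1675 ± 158 and 1194 ± 259, and Angptl4 differed by -0.23 ± 0.09. Oxidative stress genes (0.326) included Mt2A (-0.22 ± 0.09) and Sod2 (-0.20 ± 0.09), and the list's median of 0.000865 was above 0 although camera gave the direction as lower. Apoptosis genes (0.328) included Bid (-0.15 ± 0.07), renal sodium handling genes (0.406) Slc4a4 (-0.15 ± 0.06), vasoactive mediators (0.406) Calcrl (-0.21 ± 0.08) and Npr2 (-0.16 ± 0.07), and heat shock genes (0.907) Cryab (-0.28 ± 0.08). Camera gave adjusted p-values of 0.328 for oxidative phosphorylation, 0.406 for adrenal, 0.439 for leukocyte, 0.609 for endothelial and 0.907 for glycolysis genes.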

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

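The tests on the escape genes as a set, on all X-linked genes, on liver RNA, on Rup2 and on the stroma list were chosen or settled after the values they measure had been seen; those on Kdm5c alone and on signals near the floor were set before.

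Xist had a mean signal of 56.9 in the hyperinsulinemic group and 1.2 in the normal group, outside the tested probe sets. Noise of signals near the floor is argued against: 0 other probe sets were at or under 5 in one group and at or over 40 in the other. A shift of the whole X chromosome is argued against too, since the median log2 difference of 197 X-linked genes lay -0.0146 from that of 7067 autosomal genes (permutation p = 0.0569). All 4 measured genes that escape X inactivation, Eif2s3, Pbdc1, Ddx3x and Kdm5c, were higher, which is consistent with female kidneys in the hyperinsulinemic group and male kidneys in the normal group; Kdm5c alone, at 0.236 ± 0.132, did not settle it. Fetal sex and maternal insulin cannot be separated in these samples, so either, or both, may lie behind any difference reported. Other factors that follow the groups are not excluded, since the labels give an implant for the hyperinsulinemic group only and no batch or date.

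Liver transcripts and Rup2 were higher in the hyperinsulinemic group. Of 20 liver genes measured, 17 had their highest signal in hyperinsulinemic replicate 6, or 85%, against 11.9% of all probe sets, which may reflect liver RNA in that sample; 3 of the 20 reached the 40th percentile on all normal arrays. Against this, Afp was 706 in replicate 6, the lowest of the 10 arrays, although its high level elsewhere would hide a small share. One array is not the whole cause of the Rup2 difference, which was 2.87 ± 0.404 without replicate 6. One liver source for Rup2 stays open, as do maternal insulin and fetal sex, which were not tested: the log2 ratio of Rup2 to Alb was 0.323 to 1.19 in the hyperinsulinemic group and 1.27, 0.297, -0.791, -5.46 and -1.18 in normal replicates 1 to 5, but the lowest rests on 1 array where Rup2, at 19.1, was under the 40th percentile of 86.5.

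Interstitial stroma genes were lower in the hyperinsulinemic group. No single array accounts for this, the highest adjusted p without any one of them being 0.000705 (camera). An equal fall of all stromal markers is argued against, since the 18 members scattered from -0.627 to 0.0841. The scatter gave a Cochran Q p = 5.72e-09, which is no permutation test and treats genes as independent. How far that moves this p was not tested. A lower share of stromal cells stays open, because it need not lower all markers alike: 2 of the 18 are also in another list. Dilution by liver RNA cannot be told apart by the test made. With the liver score as a covariate the median moved from -0.137 to -0.0564, which met the bound first set for it. The list still passed (camera, adjusted p = 0.00275), a condition added once that median was known. Dilution would also lower other kidney genes. The proximal tubule and loop of Henle lists fell, at medians of -0.06 and -0.13. Those of the nephron progenitor, podocyte and collecting duct lists did not, at 0.01, 0.02 and 0.01. The covariate, with means of 6.14 and 6.81 (exact permutation p = 0.119), takes up part of any group difference; without the 2 arrays with the most Alb the median was -0.113 (camera, adjusted p = 0.000738), and an effect of maternal insulin or fetal sex may remain.

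Single arrays stood apart from their group in 19 of 204 groups of values examined, where chance alone would give about 10; each value is the gap to the nearest array divided by the range of the group. Normal replicate 4 stood apart for the liver genes Alb (0.872), Ttr (0.82), Hp (0.794), Serpina1 (0.759) and Fgg (0.722), for the mean of the liver list (0.933) and for Calcrl (0.758). Normal replicate 3 stood apart for F3 (0.935), at a signal of 306, normal replicate 1 for the mean of the extracellular matrix list (0.73) and normal replicate 2 for that of the vasoactive list (0.809). Among the hyperinsulinemic arrays, replicate 7 stood apart for Aqp3 (0.791), Top2a (0.742) and the mean of the cell cycle list (0.766), and replicate 8 for Mcm3 (0.83) and Slc5a2 (0.754). Replicate 10 stood apart for Cpt1a (0.752) and the mean of the fatty acid oxidation list (0.729), replicate 9 for Bid (0.756) and replicate 6 for Insr (0.787).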

How the results depend on the processing

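Omitting the arrays with the most Alb, the liver covariate and camera with an intensity trend were chosen after seeing the data. No paired analysis was possible because the labels name no litter, mother, batch or date by which samples could be paired. The sex covariate was not run, since Xist split the arrays exactly as the groups do, and the variance models without the trend and with robust estimation were not run for lists, as plain camera has neither. Of 1609 comparisons of a named gene with its main result, 1585 kept direction and side of the threshold, 5 became stronger, 10 weaker and 9 reversed; for lists, of 799 comparisons 679 were kept, 29 became stronger, 53 weaker and 38 reversed. The interstitial stroma list passed in all settings run, with adjusted p from 1.02e-06 to 0.0316. Apart from settings that test fewer arrays or another number of probe sets, the cause of each change was not tested. Dim genes are limited by the array's floor.

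The count of 1 probe set became 3 at an adjusted p under 0.1, 2 with a common median (2 higher, 2 with a fold of at least 1.5), 4 with array weights (4 higher, 3 by that fold) and 5 without a filter (4 higher, 1 lower, 4 by that fold, and 828 at an unadjusted p under 0.05). It became 0 in the rank test (whose smallest p, 0.00794, was too large for any call here), without the intensity trend (0 higher, 0 by that fold), without the 2 arrays with the most Alb (0 and 0) and with the liver covariate (0 and 0). In these last settings Rabepk was at 0.62 (0.0767) and 0.64 (0.0780), against 0.59 in the fit reported. With a pseudocount of 32 it was 1, with 0 by that fold. Leaving out each array gave 0 to 4 probe sets, 0 to 3 higher, 0 to 1 lower and 0 to 3 by that fold. The probe sets without a filter were Rabepk, Pbdc1, Xist, Lrguk (lower) and 1 unnamed.

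The 10 lists (3 higher, 7 lower) became 13 with an intensity trend in camera, 5 of them higher, adding ribosomal, erythroid and smooth muscle genes. With a pseudocount of 32, 5 were higher. With an estimated correlation 1 list passed, 0 higher and 1 lower, and adjusted p was 0.266 for liver, 0.27 for proximal tubule and immediate early, 0.25 for lipid synthesis, extracellular matrix and nerve, 0.071 for cell cycle, 0.117 for loop of Henle and 0.42 for hypoxia. The estimate was -0.0143 for loop of Henle, -0.0572 for nerve and 0.00258 for cell cycle, under the preset 0.01. A higher correlation is thus not why those lists lost their calls. The other lists that lost theirs had estimates of 0.0595 to 0.619. With fry 2 lists passed, 1 in each direction; adjusted p was 0.276 for liver and immediate early, 0.245 for proximal tubule, 0.196 for lipid synthesis and extracellular matrix, 0.0884 for loop of Henle, 0.446 for hypoxia and 0.17 for nerve. Fry's mixed test passed 1, with 0.404 for liver, proximal tubule and cell cycle, 0.0659 for lipid synthesis, 0.409 for extracellular matrix, 0.501 for loop of Henle, 0.517 for hypoxia, 0.586 for immediate early and 0.752 for nerve.

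The nerve and immediate early lists lost their calls with the Gapdh covariate (0.0545 both), the mean of probe sets (0.205 and 0.0509) and no filter (0.129 both); the nerve list also with array weights (0.0953) and without the 2 arrays with the most Alb (0.243), and the immediate early list with the stricter filter (0.493). The loop of Henle list lost its call without those arrays (0.0777). With the liver covariate the calls of hypoxia (0.252), immediate early and nerve (0.167 both) and loop of Henle (0.0607) were lost, while the median log2 difference went from -0.11 to -0.12 for nerve and from -0.13 to -0.10 for loop of Henle.

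Of the lists that did not pass at first, those that passed under another setting were smooth muscle without a filter (0.0164), with the stricter filter (0.00979), array weights (0.0362) and the camera trend (0.0367), and erythroid with a common median (0.0435), a pseudocount of 32 (0.0472), no filter (0.00518), array weights (0.046), without the 2 arrays (0.0405) and with the camera trend (0.0367). Ribosomal genes passed with a pseudocount of 32 (0.0483) and the camera trend (0.0314), fatty acid oxidation with array weights (0.0372), oxidative phosphorylation with the liver covariate (0.018), and glucocorticoid-responsive genes with it (0.046) and without the 2 arrays (0.0403).

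With all arrays or without those 2, these lists reversed, none past the threshold: glycolysis with array weights (0.674), cyclic loess (0.83), the mean of probe sets (0.965), no filter (0.736), quantile normalization (0.77) and without the 2 arrays (0.579); podocyte with array weights (0.941) and without the 2 arrays (0.801); leukocyte with the liver covariate (0.921) and no filter (0.736); nephron progenitor with the liver covariate (0.652), no filter (0.736) and without the 2 arrays (0.738); ribosomal with quantile normalization (0.646); endothelium (0.964) and ureteric bud (0.971) with the stricter filter. Named genes that reversed were Insr with array weights (0.00442), the liver covariate (0.0802) and without the 2 arrays (0.0115), Igf2 with the liver covariate (0.00372) and Serpina1 with it (-0.0266), as log2 differences.

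Leaving out each array gave 3 to 6 lists higher and 4 to 8 lower. Adjusted p ran from 0.000266 to 0.345 for hypoxia, 0.0134 to 0.149 for immediate early, 0.0122 to 0.124 for nerve, 3.21e-05 to 0.941 for ribosomal, 0.00812 to 0.557 for oxidative phosphorylation, 0.101 to 0.964 for glycolysis, 0.643 to 0.995 for nephron progenitor, 0.182 to 0.85 for skeletal muscle, 0.382 to 0.899 for ureteric bud, 0.409 to 0.962 for podocyte and 0.259 to 0.935 for heat shock genes. Oxidative phosphorylation genes were higher without hyperinsulinemic replicate 7 (0.0172) and lower without replicate 10 (0.00812). Of the lists that did not pass with all arrays, those that passed without 1 array were smooth muscle, without normal replicate 1 (0.0256) or 5 (0.0202) or hyperinsulinemic replicate 10 (0.0256); erythroid, without normal replicate 3 (0.0329) or 4 (0.0309) or hyperinsulinemic replicate 7 (0.0363) or 8 (0.0352); ribosomal, without normal replicate 4 (0.00723) or hyperinsulinemic replicate 7 (3.21e-05) or 8 (0.0291); oxidative phosphorylation, also without hyperinsulinemic replicate 6 (0.0405); and fatty acid oxidation, without hyperinsulinemic replicate 10 (0.0157). Among named genes Rup2 passed with a common median (0.0412), with array weights (0.0158) and without hyperinsulinemic replicate 6 (0.0321) or 10 (0.0297), and Lum without normal replicate 5 (0.0310). The median log2 difference of the hypoxia list was -0.02 without normal replicate 3 and with the liver covariate, and -0.09 without normal replicate 4 and without the 2 arrays with the most Alb. That of the immediate early list was -0.02 with the liver covariate, -0.04 without a filter and 0.00493 with the stricter filter, and that of the nerve list -0.04 without a filter and without the 2 arrays. Without a filter that of the loop of Henle list was -0.07, and with the stricter filter that of lipid synthesis 0.10. Single arrays moved other named genes by over 1.5 times, none past the threshold: without normal replicate 3, Ccn1 was at -0.35, Ankrd37 at -0.17, Gadd45b at -0.14, Bnip3 at -0.11 and Rtn1 at -0.10; without normal replicate 4, Nefl was at -0.08, Nefm at -0.03 and Agtr1a at -0.03; without normal replicate 5, Egr1 was at -0.13; and without hyperinsulinemic replicate 10, Agtr2 was at -0.09, Dusp6 at -0.11 and Pmp22 at -0.09, and without replicate 7 Mt2A was at -0.14. Insr ran from -0.049 to 0.0356 and Igf2 from -0.0777 to 0.0233.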

Other observations

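The split of the lipid synthesis list into arms was tested after its leading genes had been seen; the counts over other splits of the arrays were set before.

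Within lipid synthesis, the 7 measured genes of the fatty acid arm were higher by a mean log2 difference of 0.153 (exact permutation p = 0.0159), and the 16 of the sterol arm by 0.0559 (exact permutation p = 0.246). The arms were set apart because the 4 genes that passed over the list alone are fatty acid genes, so their difference of 0.0971 restates that observation. Without those 4, the 3 fatty acid genes left differed from the sterol arm by -0.0602 (exact two-sided permutation p = 0.19), and a shift of the whole fatty acid arm was not shown.

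Among X-linked genes, 6 of 197 had an unadjusted p under 0.01, or 3.05%, against 71 of 7067 autosomal genes, or 1% (Fisher's exact test across genes, p = 0.0177, chosen after the X-linked genes had been seen; genes are not independent replicates). The secreted liver genes Orm1 and Hpx, which are outside the fixed list and were picked after their values were seen, stood at 42.1 ± 11.6 and 222 ± 233 and at 57.2 ± 12 and 199 ± 180 (SD, n = 5 each, exact permutation p = 0.00794 and 0.0159). Both were highest in hyperinsulinemic replicate 6, at 634 and 504, and without it the hyperinsulinemic means were 119 ± 39 and 122 ± 65.3 (SD, n = 4). In normal replicate 4, where Alb was 842, they were 38 and 62.5, within the range of the other normal arrays.

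The arrays can be divided into 2 groups of 5 in 126 ways, of which 100 were drawn, the real one included. A chance division is not excluded for the 1 probe set past the threshold, since 6 of the 100 gave as many, the highest of the others being 2. It is not excluded for the 515 probe sets at an unadjusted p under 0.05, which 34 reached; the highest other count, 1243, put normal replicates 1 and 3 with hyperinsulinemic replicates 7, 8 and 9. These were the 5 arrays with the lowest 3' to 5' ratio of the Gapdh controls, 1.02 to 1.06 against 1.09 to 1.18 on the others, a match seen afterwards and not tested. Whether the samples have a structure that the groups do not follow was thus not shown. With the ratio as a covariate, the real groups gave 1 probe set, 575 at an unadjusted p under 0.05 and 8 lists. Nor is it excluded for the 10 lists, since 6 of the 100 gave as many, the real one included. The highest of the others was 11, with a median of 4. A split that gave 11 put normal replicate 1 with hyperinsulinemic replicates 6, 8, 9 and 10. It exchanges 1 array of each group, so it may carry part of the real difference. With an intensity trend in camera, added later, the real split gave 13 lists, which 1 of the 100 reached, the highest other being 12. With an estimated correlation the real split gave 1 list, and 2 of the 100, the real one included, gave at least 1, the highest other being 1. Counts as large were thus rare among the splits in these last settings. The trend, however, was added after the plain results were seen. The count of 1 list with an estimated correlation was matched only by the split of normal replicate 1 with hyperinsulinemic replicates 6, 8, 9 and 10. Because that split lies so close to the real groups, the match is weak evidence for a chance division. A chance division is therefore not excluded for the number of lists in the form reported, and these last settings do not settle it.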
